A study of Homo sapiens with 15 samples.

How the data were processed

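RNA was measured in 15 libraries of the MCF10AER/vSrc cell line, in 3 groups of 5 that were taken from the treatment and title labels. Per the labels' protocols, RNA was extracted with an RNeasy kit and libraries were made with Illumina's stranded total RNA kit. Per the submitters' processing notes, the authors used STAR 2.5.2b, featureCounts, Subread 1.5.1 and edgeR, with genome build hg38. The strand setting of the counting, the annotation release and the exact order of steps are not given in the sources used here. The values of genes whose exons overlap a gene on the other strand, and of genes with near-identical copies, are therefore uncertain.

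The authors deposited 1 table of 64253 genes with an RPKM value per library (reads scaled by gene length and library total), although the name of the table speaks of counts. That the unit is RPKM was read from the values: multiplied by gene length, they add up to the same total in every library. Each value was a whole multiple of what 1 read was worth in that library, so reads were recovered from the steps. Of the values above 0, 100% lay within 0.01 of a whole number of reads. Recovered totals ran from 8523761 to 15463949 reads, which sets the precision of low genes. For genes with 0 reads, the upper limit is the level of 3 reads in the group, and such limits cover counting error only.

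The design fixed before the data were examined assumed raw counts and the authors' tool edgeR. Because the deposited unit is RPKM, which is not a count, the test was limma 3.58.1 in R 4.3.3 instead. Values were divided by a trimmed-mean composition factor per library, computed here from the recovered reads (30% of log ratios and 5% of mean levels trimmed at each end), and taken as log2(RPKM + 0.1). A gene was tested where at least 5 libraries had 0.5 RPKM or more and 10 reads or more, which left 14141 genes. All 15 libraries entered 1 fit with a mean per group and an intensity trend in the empirical Bayes step. Adjusted p-values are Benjamini-Hochberg values over all tested genes, with a threshold of 0.05, and all tests are 2-sided. Folds on this scale understate changes of genes near 0. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

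Groups, comparisons, gene lists, the rule for named genes and most alternatives were chosen before the data were examined, and 4 further gene lists in the closing observations were written after some values had been seen. The 34 gene lists cover oxidant and stress responses, metabolism, cell cycle, histone H3 genes, epithelial and mesenchymal identity, drug resistance and markers of other cell types. Of these, 31 had at least 5 tested members and were tested with camera (limma) at a preset inter-gene correlation of 0.01, with an estimated correlation and the rotation test fry as alternatives. Named genes were the 10 largest rises and 10 largest falls per comparison among protein-coding genes with an adjusted p under 0.05 and a mean log2 CPM of at least 1. To these were added up to 4 members per list with the smallest p and a fixed set of oxidant, p53, histone, epithelial, drug efflux and cell cycle genes. Gene positions are those of GENCODE release 29 on hg38.

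The numbers of the replicates were shared by the groups, but the labels do not say that a number marks a shared culture or day, so they were not used as pairs. Changes shared by both times were set against independent lists of the same sizes, against 100 simulated sets of unchanged groups compared with the same controls, and against 20 splits of the controls between the comparisons. Library measures were compared with exact permutation tests over the 252 regroupings.

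The steps were tested on simulated data drawn for 14105 genes in the 4 h against control comparison at a dispersion of 0.0021. Of genes changed 1.5-fold, 63 of 67 were called, of those changed 2-fold 63 of 67, and of those changed 4-fold 66 of 66. Of 13905 unchanged genes, 9 were called at 4 h, and at 24 h 0 unchanged genes were called. The changed genes were few, went up and down in balance, and did not include genes with few reads. In the data 66% of genes changed at 4 h. The simulation therefore tests neither the scaling under so wide a change nor changes of low genes. A simulated list of raised genes had a camera p of 4e-157 and a list of 30 unchanged genes one of 0.81.

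Alternatives were other composition factors, no filter and another filter, limma-voom on recovered reads and a fit of only the groups compared. The replicate number as a block and leaving out each library in turn were alternatives too. The other filter, a CPM of at least 1 in 5 libraries, left 14724 genes. Chosen after seeing the data were the absence of a composition factor, pseudocounts of 0.01 and 1, and leaving out near-identical gene families. Tests on counts by the authors' tool edgeR were not run because the deposited unit is RPKM. Running the scaling, filter and voom settings on gene lists and shared genes was also added then. GC content and transcript length, taken from the transcripts of 13853 tested genes, were corrected per library with splines in a separate check. Libraries of a group differed by more than sampling noise (chi-square per gene 1.739 to 5.995 between pairs), so no pair was taken as repeat reads of 1 library. That does not show separate cultures. Each library was counted as 1 replicate, and no sample was left out.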

Results

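Gene expression was measured by RNA sequencing in MCF10AER/vSrc cells, a derivative of the non-tumorigenic human breast epithelial line MCF10A that carries the v-Src oncoprotein fused to the ligand-binding part of the oestrogen receptor. The 15 libraries formed 3 groups of 5: untreated control cells, cells 4 h after addition of D-alanine and cells 24 h after addition of D-alanine, at 10 nM per the labels. That dose is far below the millimolar range usual for D-alanine with an oxidase, and whether its unit is right could not be settled here. The series text describes the treatment as a source of nuclear reactive oxygen species, which were not measured here, and the series title names histone H3.1 as a redox sensor, phenotypic plasticity and drug resistance. The labels give no time for the control cells, and they do not say that the 5 libraries of a group came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical. Reads assigned to genes numbered 9482638 to 13995828 in control libraries, 10980578 to 15463949 at 4 h and 8523761 to 13736749 at 24 h. Of 64253 annotated genes, 14141 were expressed at a level that allowed a test.

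The 4 h libraries stood far apart from the other groups on the first principal component, which held 71.4% of the variance, and the second component (6.71%) separated 24 h from control. Correlations of log2 expression across genes were 0.988 to 0.993 within groups, 0.937 to 0.947 between 4 h and control, and 0.981 to 0.988 between 24 h and control. Library measures moved with the groups as well. Mitochondrially encoded transcripts took 3.81% ± 0.376 of reads in controls, 2.53% ± 0.466 at 4 h and 3.51% ± 0.238 at 24 h (SD, n = 5; 2-sided exact permutation p = 0.0079 for 4 h against control, 0.17 for 24 h against control and 0.0079 between the times). Genes with at least 1 read numbered 21590 ± 364 in controls, 20550 ± 460 at 4 h and 21340 ± 533 at 24 h (SD, n = 5; exact permutation p = 0.024, 0.4 and 0.048). The 10 most abundant genes took 6.99% ± 0.128, 7.96% ± 0.0652 and 7.24% ± 0.127 of reads (SD, n = 5; exact permutation p = 0.0079, 0.016 and 0.0079). After Benjamini-Hochberg adjustment over the 9 such comparisons these exact p-values were 0.018, 0.19 and 0.018 for the mitochondrial share, 0.036, 0.4 and 0.062 for genes detected, and 0.018, 0.029 and 0.018 for the 10 most abundant genes.

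**Figure D1:**
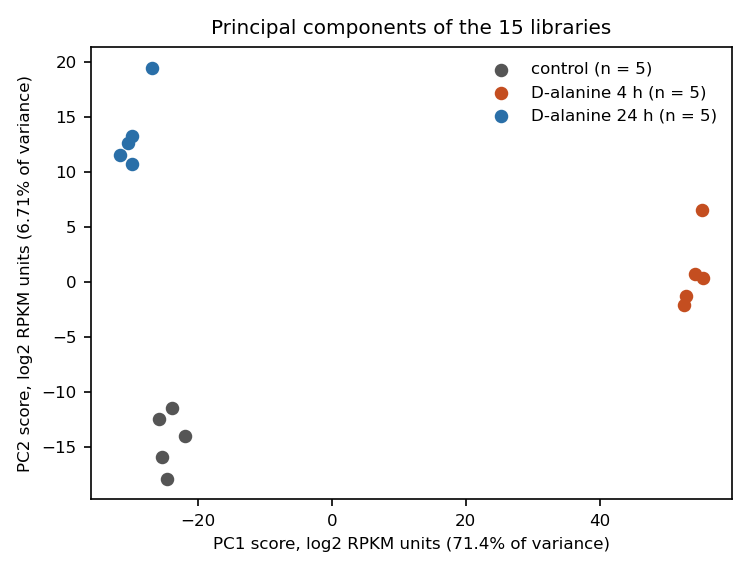
Scores of the 15 libraries on the first (x axis) and second (y axis) principal components of log2 RPKM, 1 point per library, coloured by group. The 5 libraries at 4 h lie between 52.7 and 55.4 on the first component, control libraries between -25.8 and -22, and 24 h libraries between -31.6 and -26.9.

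At 4 h CLDN4, a tight junction claudin, rose from 0.143 ± 0.0634 to 21.5 ± 3.37 RPKM (SD, n = 5), and CGN, the junction plaque protein cingulin, from 0.176 ± 0.0574 to 5.39 ± 0.444 RPKM. ALDH1A3, a retinaldehyde dehydrogenase, rose from 4.5 ± 0.285 to 211 ± 11.9 RPKM, and FST, the activin antagonist follistatin, from 0.326 ± 0.0714 to 34.8 ± 2.81 RPKM. These 4 were among the 10 largest rises of protein-coding genes with a mean log2 CPM (counts scaled to library size) of at least 1, the filter for all such rankings. IL1B, the inflammatory cytokine interleukin-1 beta, rose from 12.1 ± 0.461 to 206 ± 9.62 RPKM and was not among them. The largest fall was that of TP73, a transcription factor of the p53 family, from 4.24 ± 0.263 to 0.155 ± 0.0502 RPKM, followed by VAV3, a guanine nucleotide exchange factor, from 8.33 ± 0.557 to 0.803 ± 0.142 RPKM.

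These changes were far larger than the spread between replicates. CLDN4 (ENSG00000189143, hg38 chromosome 7, 73799542 to 73832693) changed by 6.66 ± 0.18 on the log2 scale (SE; limma adjusted p = 2.7e-14), with 16.2 to 24.8 RPKM across treated libraries and 0.0448 to 0.213 RPKM across controls. ALDH1A3 (ENSG00000184254, chromosome 15, 100877714 to 100916626) changed by 5.70 ± 0.052 (SE; limma adjusted p = 4e-20). FST (ENSG00000134363, chromosome 5, 53480409 to 53487134) changed by 6.53 ± 0.25 (SE; limma adjusted p = 2e-12) and TP73 (ENSG00000078900, chromosome 1, 3652520 to 3736201) by -3.97 ± 0.12 (SE; limma adjusted p = 6.3e-14). The other genes among the 10 largest rises were SPRR2D and SPRR2A, cornified envelope precursors (log2 6.14 and 5.20), PLA2G4E, a cytosolic phospholipase (5.51), the transcription factor OVOL1 (4.97), and the adjacent serpins SERPINB2 and SERPINB10 (4.67 and 4.62). The other large falls were those of GCSAM, ZNF608, BEST1, FIBIN, GRAMD2, MAB21L3, MYCL and SRGAP3, with log2 changes from -2.91 to -2.48. Values on the log2(RPKM + 0.1) scale understate the change of genes near 0, such as CLDN4. SERPINB2 shares exonic sequence on the same strand with SERPINB10, and 12.6% of the 50-base words of SPRR2D also occur in SPRR2A, so reads of each pair are only partly separable. ALDH1A3, TP73, GCSAM, BEST1 and SRGAP3 overlap exons of a gene on the other strand, and whether strand was used in counting is not given in the sources used here. The values of CD68, CRYAB, CYP1B1, DDIT3, ENTPD3, EPHX1, FANCA, FEN1, H3F3B, KIF20A, KRT8 and KRT18 are uncertain for the same reason, as are those of LOX, MCM2, MDM2, SOD2, TAGLN, TNFRSF6B, VIM and ZEB1. Exons of ALDH1A3, BRCA1, CD68, FEN1, HSPA8, MDM2, MT-ND4, SAA2 and SRXN1 overlap a gene on the same strand.

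In all, 9339 of 14141 genes changed at 4 h (limma adjusted p under 0.05), 4723 higher and 4616 lower. The change was at least 2-fold for 668 genes that rose and 702 that fell, and at least 4-fold for 186 and 60. The split depends on the scaling: 50.6% of changed genes were higher with trimmed-mean factors and 30.4% with the deposited RPKM used without a composition factor, which moved the median of all genes by -0.17. Log2 changes are given relative to the trimmed-mean scaling, and they lie above the ratio of the printed RPKM means, which are as deposited, by about that shift. VIM, an intermediate filament protein of mesenchymal cells, shows it. Its log2 change of 0.21 ± 0.034 (SE; limma adjusted p = 5.5e-05) belongs to means of 157 ± 2.92 and 154 ± 4.24 RPKM (SD, n = 5) and was 0.03 (limma adjusted p = 0.42) without the factor.

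Genes of the endoplasmic reticulum rose together at 4 h. Of 25 chaperone and unfolded protein response genes, 24 were higher and 0 lower, over all genes and adjusted over the list alone, with a median log2 change of 0.55 (camera adjusted p = 2.4e-09). Of the 31 lists chosen before the data were examined, only this call held at 4 h with an estimated correlation (adjusted p = 0.017). HSPA5, the main chaperone of the endoplasmic reticulum, rose from 113 ± 2.42 to 270 ± 11.2 RPKM (SD, n = 5). XBP1, a transcription factor of the unfolded protein response, rose from 20 ± 0.821 to 55.6 ± 1.35 RPKM, and HERPUD1 from 7.42 ± 0.493 to 18.5 ± 0.577 RPKM. DDIT3, a stress-induced transcription factor that is often raised with these genes, had a log2 change of 0.06 ± 0.11 (SE; limma adjusted p = 0.66), and ATF3, another such factor, one of -0.44 ± 0.19 (SE; limma adjusted p = 0.051). Of 21 heat shock protein genes, 17 were higher and 2 lower on both adjustments, including HSPH1 (log2 1.04) and HSPA8 (0.97), with a camera adjusted p of 6.1e-05 (adjusted p = 0.18 with an estimated correlation). With the preset correlation 14 of 31 lists passed at 4 h, 16 at 24 h and 21 between the times, and other splits of the libraries passed up to 15, 16 and 21. Those splits keep part of the difference between the groups, so they do not measure chance.

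Epithelial and squamous genes were mostly higher at 4 h. Of 25 genes of epithelial identity, 22 rose and 3 fell on both adjustments, with a median of 0.94 (camera adjusted p = 6.1e-08; adjusted p = 0.12 with an estimated correlation). CDH1, the adherens junction protein E-cadherin, rose from 44.6 ± 2.21 to 114 ± 5.96 RPKM (SD, n = 5), and CLDN1, a claudin of tight junctions, reached 181 ± 8.69 RPKM (log2 change 3.84). Of 29 basal and squamous genes, 22 rose and 4 fell (23 and 4 adjusted over the list alone), with a median of 0.79 (camera adjusted p = 1.1e-05; adjusted p = 0.18 with an estimated correlation). KRT6B, a keratin of activated keratinocytes, rose by 3.96 and SFN, the 14-3-3 sigma protein, by 1.54, whereas TP63, the basal cell transcription factor, fell by 1.42 on the log2 scale. KRT6B has near-copies in KRT6A and KRT6C, so its reads are partly uncertain. Of 9 luminal breast markers, 8 rose and 1 fell on both adjustments, including KRT8 (1.60) and KRT18 (1.14), with a median of 1.15 (camera adjusted p = 0.0013; adjusted p = 0.12 with an estimated correlation). That list includes ESR1, part of which the fusion transgene also carries.

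Several signalling lists also rose at 4 h, and none of their calls held with an estimated correlation. Of 22 TGF-beta and SMAD target genes, 17 rose and 1 fell on both adjustments (camera adjusted p = 0.0011; adjusted p = 0.19 with an estimated correlation), among them PMEPA1 (1.22). Of 23 YAP and TAZ target genes, 17 rose and 5 fell on both adjustments (camera adjusted p = 0.008; adjusted p = 0.27 with an estimated correlation), with F3, the coagulation starter tissue factor, up by 3.21 and NT5E by 2.26. Of 24 immediate early genes, 16 rose and 7 fell on both adjustments (camera adjusted p = 0.021; adjusted p = 0.41 with an estimated correlation). FOSL1 (2.49) and the phosphatase gene DUSP4 (2.02), both of which respond to ERK signalling, rose, and EGR1 (-1.44), FOSL2 (-1.24) and FOS (-0.48) fell. Of 6 metallothionein-list genes, 5 rose on both adjustments, and adjusted over the list alone 1 also fell (camera adjusted p = 0.021; adjusted p = 0.18 with an estimated correlation), with MT1E at 0.91 and the zinc exporter SLC30A1 at 1.18. Of 16 glycolysis genes, 11 rose and 2 fell on both adjustments (camera adjusted p = 0.018; adjusted p = 0.59 with an estimated correlation), and without a composition factor the camera adjusted p was 0.17.

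Of 19 stem and plasticity-associated genes, 12 rose and 6 fell on both adjustments (camera adjusted p = 0.049; adjusted p = 0.18 with an estimated correlation). SOX9, a transcription factor of progenitor cells, rose from 0.582 ± 0.0812 to 11.7 ± 1.09 RPKM and CD24, a surface glycoprotein, from 89.8 ± 3.54 to 210 ± 7.32 RPKM (SD, n = 5). This list's call was lost when control replicate 1, 3 or 4 or 4 h replicate 3 or 5 was left out (camera adjusted p = 0.054, 0.059, 0.051, 0.061 and 0.051). It was also lost under median-of-ratios factors (0.052) and the filter on a CPM of at least 1 in 5 libraries (0.096).

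Genes of mitosis and p53 targets were mostly lower at 4 h. Of 41 G2 and mitosis genes, 31 fell and 2 rose (32 and 2 adjusted over the list alone), with a median of -0.32 (camera adjusted p = 3.2e-06; adjusted p = 0.47 with an estimated correlation). The mitotic kinesin KIF20A fell by 1.21, the phosphatase CDC25B by 1.08 and the topoisomerase TOP2A by 0.91 on the log2 scale. Of 30 p53 target genes, 20 fell and 9 rose (20 and 10 adjusted over the list alone), with a median of -0.51 (camera adjusted p = 0.021; adjusted p = 0.23 with an estimated correlation; 0.13 without a composition factor). SESN1 fell from 15.9 ± 0.972 to 3.54 ± 0.121 RPKM and GDF15 from 4.55 ± 0.509 to 0.948 ± 0.145 RPKM (SD, n = 5). CDKN1A, the cell cycle inhibitor p21, rose from 61.8 ± 1.9 to 93.7 ± 4.51 RPKM and GADD45A from 14.2 ± 0.987 to 34.8 ± 1.49 RPKM (SD, n = 5), and MDM2, which encodes the ubiquitin ligase of p53, fell by 0.15 on the log2 scale. Of 13 mitochondrially encoded transcripts, 10 fell and 0 rose on both adjustments, MT-ND4 by 0.62 and MT-CYB by 0.53, with a median of -0.46 (camera adjusted p = 0.024; adjusted p = 0.68 with an estimated correlation; 0.068 without a composition factor). These transcripts are also the mitochondrial share of reads that was lowest at 4 h, and it was 1.74% in 4 h replicate 1.

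Oxidant defence genes went both ways at 4 h. Of 30 NRF2 target genes, 9 rose and 13 fell on both adjustments, and the list did not pass (camera adjusted p = 0.61, towards lower values like its median of -0.08, with a mean of 0.02). HMOX1, haem oxygenase, rose from 1.65 ± 0.299 to 2.77 ± 0.329 RPKM and NQO1, a quinone reductase, from 48.8 ± 0.823 to 57.3 ± 2.22 RPKM, whereas TXNRD1 (log2 -0.25), SLC7A11 (-0.43), GSR (-0.82) and the glutathione conjugate pump ABCC2 (-1.20) fell. Of 25 peroxide and superoxide removal genes, 7 rose and 10 fell on both adjustments (camera adjusted p = 0.27), and SOD2, the mitochondrial superoxide dismutase, fell from 72.2 ± 3.71 to 29.6 ± 1.46 RPKM (SD, n = 5).

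The other lists did not pass at 4 h (camera adjusted p in brackets). DNA repair had 10 higher and 16 lower of 43 (camera adjusted p = 0.49), and DNA replication 9 and 15 of 41 (0.44), each on both adjustments. The test of the replication list pointed towards lower values like its mean of -0.05, with a median of 0.03. NF-kB and inflammatory genes had 12 higher and 9 lower of 25 on both adjustments (0.63), with IL1B higher and BIRC3 (-2.32) and NFKBIA (-0.98) lower. Mesenchymal genes had 13 higher and 5 lower of 31 on both adjustments (0.25), with ITGA5 (1.84) and TAGLN (2.49) higher, and with log2 values of 0.12 for FN1 (limma adjusted p = 0.077) and -0.06 for SNAI2 (0.26). The transcription factor gene ZEB1 rose by 0.68, from 0.495 ± 0.0441 to 0.754 ± 0.0613 RPKM, and SRC, the cellular gene related to v-Src, by 0.50, from 15 ± 0.826 to 18.7 ± 0.842 RPKM (SD, n = 5). Whether reads of the v-Src fusion transgene were counted in SRC was not examined. Drug efflux and metabolism had 7 higher and 13 lower of 25 on both adjustments (0.38, median -0.13 and mean 0.06). The integrated stress response list had 13 higher and 11 lower of 29, and 13 and 12 adjusted over the list alone (0.8), and interferon-stimulated genes 13 and 9 of 29 on both adjustments (0.48). Hypoxia genes had 10 and 10 of 24, and 10 and 11 adjusted over the list alone (0.99, towards higher values like its mean of 0.26, with a median of -0.02). Cholesterol synthesis had 15 and 8 of 25 on both adjustments (0.23), fatty acid synthesis 4 and 9 of 18 on both adjustments (0.18), and stromal markers 1 and 2 of 6 on both adjustments (0.45). Nuclear-encoded oxidative phosphorylation had 1 and 10 of 38, and 1 and 9 adjusted over the list alone (0.25), and ribosomal proteins 1 and 4 of 74, and 1 and 1 adjusted over the list alone (0.32). Without a composition factor those last lists passed as lower (0.00067 and 3.2e-06), and the medians of the DNA replication, NF-kB, mesenchymal, integrated stress response and interferon lists turned from above to below 0.

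Of the 10 replication-dependent H3.1 genes, only HIST1H3E and HIST1H3H had enough reads for a test, with 766 reads for the list over all libraries, and the copies are so alike in sequence that reads may be split between them. HIST1H3E fell from 3.86 ± 0.759 to 1.23 ± 0.531 RPKM at 4 h and HIST1H3H from 1.54 ± 0.405 to 0.606 ± 0.255 RPKM (SD, n = 5; limma adjusted p = 4.6e-05 and 0.00032). At 24 h they stood at 4.8 ± 0.968 and 2.16 ± 0.351 RPKM, which did not pass against control (limma adjusted p = 0.39 and 0.12, with 1 of the pair at an unadjusted p under 0.05 and 0 called by limma-voom). Of 49 other replication-dependent histone genes only 9 could be tested, of which 0 rose and 3 fell at 4 h on both adjustments (camera adjusted p = 0.38). Both histone lists thus cover few of their members, at both times, and do not stand for histone expression as a whole. Of 21 genes for H3.3 and H3 chaperones, 6 rose and 6 fell on both adjustments (0.61). H3F3B, which encodes the replacement histone H3.3, rose by 0.50 (limma adjusted p = 3.7e-10), and H3F3A had a log2 change of -0.05 (0.2), which was -0.23 (2e-06) without a composition factor.

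Few markers of other cell types had enough reads for a test. Of 10 endothelial markers 1 was tested, KDR, which was lower at 4 h (log2 -1.83), and of 14 blood and immune markers 3, of which CD68 (0.35) was higher, CSF1R (-1.19) lower and CD14 (-0.15) not passing. Those 3 stood at 8.27 ± 0.459, 3.84 ± 0.46 and 10.9 ± 1.04 RPKM in controls, in the same order (SD, n = 5). DAO, the D-amino acid oxidase that releases hydrogen peroxide from D-alanine, had 0 reads in all 15 libraries, which allows up to 0.051, 0.049 and 0.052 CPM in the control, 4 h and 24 h groups. The labels name no oxidase construct, and a coding sequence outside the annotated genome would not be counted here. ABCB1, the drug efflux pump P-glycoprotein, had 0 reads in all 15 libraries, with the same limits, and ABCG2, another efflux pump, had 7, 19 and 9 reads in the 3 groups. These limits cover counting error only.

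**Figure D2:**
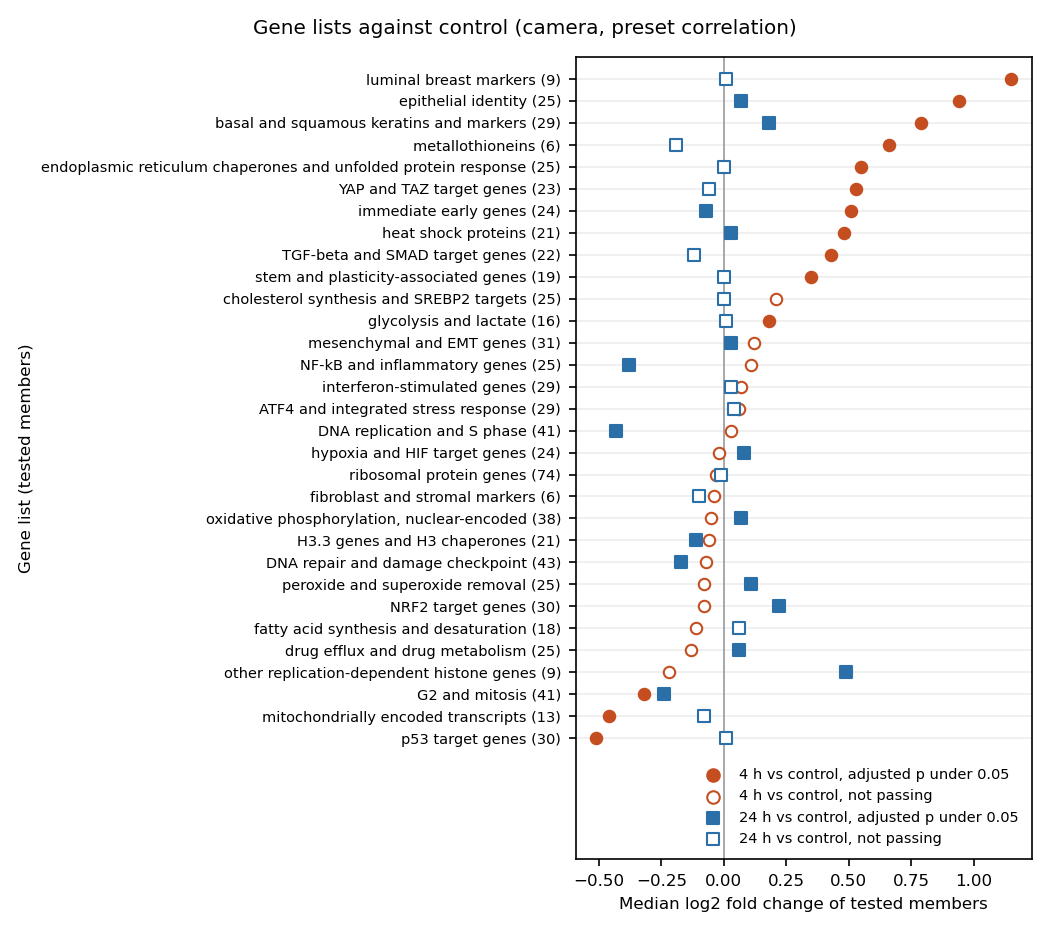
Median log2 fold change (x axis) of the tested members of each gene list (y axis, number tested in brackets) at 4 h (circles) and 24 h (squares) against control, filled where camera with the preset correlation gave an adjusted p under 0.05. The epithelial identity list lies at 0.94 at 4 h and 0.07 at 24 h, and the DNA replication list at 0.03 and -0.43; without a composition factor the 4 h medians lie lower by about 0.17, which puts that of DNA replication below 0.

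At 24 h, S100A9 and S100A8, calcium-binding proteins of inflamed epithelium, showed the largest falls against control, from 730 ± 38.4 to 231 ± 18.9 RPKM and from 318 ± 25.6 to 114 ± 10.8 RPKM (SD, n = 5). Both had been higher than control at 4 h (log2 0.74 and 0.63). KRT15, a keratin of basal cells, rose from 131 ± 13.6 to 262 ± 17.9 RPKM after a lower level at 4 h (56.2 ± 4.76 RPKM). HSPB1, a small heat shock protein, rose from 713 ± 64.6 to 1290 ± 111 RPKM, and GPX2, a glutathione peroxidase, from 0.147 ± 0.059 to 1.46 ± 0.361 RPKM.

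At 24 h 2573 genes differed from control, 1252 higher and 1321 lower (limma adjusted p under 0.05), of which 42 and 34 changed at least 2-fold. Without a composition factor 38% of changed genes were higher, against 48.7% with trimmed-mean factors. Under the filter of mean level, which leaves out GPX2 with its larger rise, the largest rises were in PLA2G4F, a cytosolic phospholipase (1.77 ± 0.12, SE; limma adjusted p = 1.7e-07), HSD11B2, the enzyme that inactivates cortisol (1.70 ± 0.12, SE; 1.6e-07), the secreted factor WISP2 (1.57) and the retinoic acid carrier CRABP2 (1.42). GNAO1, KRT1, ALPP, RAB26, ENTPD3 and ALDH3A1 followed, from 1.38 to 1.24. The largest falls were in S100A9 (-1.64 ± 0.07, SE; limma adjusted p = 2.2e-09), S100A8 (-1.46 ± 0.084, SE; 2.2e-08), FCAR (-1.31), the complement factor CFB (-1.30), XXbac-BPG116M5.17, which is annotated across CFB (-1.29), the decoy receptor TNFRSF6B (-1.20), KIAA1644, IL32, GALNT14 and PLA2G4E (-1.07). S100A9 (ENSG00000163220) lies on hg38 chromosome 1 at 153357854 to 153361027, PLA2G4F (ENSG00000168907) on chromosome 15 at 42139034 to 42156636 and HSD11B2 (ENSG00000176387) on chromosome 16 at 67430652 to 67437553. CFB and XXbac-BPG116M5.17 share exons on 1 strand, as do TNFRSF6B and a readthrough gene, so their reads are not independent.

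DNA replication genes were lower at 24 h. Of 41 genes, 39 fell and 0 rose (41 and 0 adjusted over the list alone), with a median of -0.43 (camera adjusted p = 4.2e-30; adjusted p = 0.014 with an estimated correlation, so the call held). CDC45, part of the replicative helicase, fell from 7.85 ± 0.368 to 4.08 ± 0.696 RPKM (SD, n = 5). MCM2, another part of it, fell from 17.2 ± 1.06 to 11.8 ± 0.416 RPKM, and RRM2, a subunit of ribonucleotide reductase, from 21.2 ± 1.84 to 13.2 ± 1.21 RPKM (SD, n = 5). MCM2 had already fallen at 4 h (log2 -0.42; limma adjusted p = 3.4e-06) and CDC45 had not (0.07; 0.543). Of 43 DNA repair genes, 16 fell and 0 rose (21 and 0 adjusted over the list alone; camera adjusted p = 2.8e-07; adjusted p = 0.029 with an estimated correlation, so the call held), including BRCA1 (-0.65), FEN1 (-0.60) and FANCA (-0.67). Of 41 G2 and mitosis genes, 27 fell and 1 rose (29 and 1 adjusted over the list alone; camera adjusted p = 7.6e-11; adjusted p = 0.22 with an estimated correlation). They included AURKB (-0.61) and CDK1 (-0.47), while CCNB1, cyclin B1, had a value of 0.04 (limma adjusted p = 0.65). Of 21 H3.3 and H3 chaperone genes, 11 fell and 1 rose on both adjustments (camera adjusted p = 5.4e-05; adjusted p = 0.067 with an estimated correlation). Those that fell included HJURP, the chaperone of the centromeric H3 variant (-0.89), and ASF1B, a chaperone of newly made H3 (-0.72), both of which are produced mainly in dividing cells. Of 9 other replication-dependent histone genes, 4 rose and 0 fell (7 and 0 adjusted over the list alone; camera adjusted p = 0.00021; adjusted p = 0.06 with an estimated correlation), HIST1H2AC by 0.49 and HIST1H2BK by 0.34.

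Inflammatory genes were lower and NRF2 target genes higher at 24 h. Of 25 NF-kB and inflammatory genes, 19 fell and 0 rose (20 and 0 adjusted over the list alone), with a median of -0.38 (camera adjusted p = 2.5e-18; adjusted p = 0.0069 with an estimated correlation, so the call held). SAA2, an acute phase protein, fell by 0.95 and TNFAIP2 by 0.58 on the log2 scale. Of 30 NRF2 target genes, 16 rose and 1 fell (20 and 1 adjusted over the list alone), with a median of 0.22 (camera adjusted p = 6.2e-09; adjusted p = 0.014 with an estimated correlation, so the call held). NQO1 rose from 48.8 ± 0.823 to 60.1 ± 1.08 RPKM, EPHX1, an epoxide hydrolase, from 40.2 ± 2.59 to 58.8 ± 3.29 RPKM, and TKT, transketolase, from 68.3 ± 3.44 to 84.4 ± 3.34 RPKM (SD, n = 5). ABCC3, an efflux pump, fell from 11.5 ± 0.38 to 6.26 ± 0.26 RPKM (SD, n = 5). HMOX1 and SRXN1 were at 0.02 and 0.07 (limma adjusted p = 0.94 and 0.24). Of 25 peroxide and superoxide removal genes, 10 rose and 1 fell on both adjustments (camera adjusted p = 0.00011; adjusted p = 0.17 with an estimated correlation), with GPX2 (2.67) and PRDX5 (0.41) higher and SOD2 (-0.69) lower.

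Keratin, hypoxia and drug metabolism lists were higher at 24 h, with calls that did not hold with an estimated correlation. Of 29 basal and squamous genes, 13 rose and 3 fell (17 and 4 adjusted over the list alone; camera adjusted p = 7.7e-05; adjusted p = 0.18 with an estimated correlation), KRT15 by 1.03 and KRT16 by 0.97, with SERPINB3 lower (-0.82). Of 24 hypoxia genes, 6 rose and 0 fell on both adjustments (camera adjusted p = 0.0067; adjusted p = 0.13 with an estimated correlation), including LOX (0.50) and the glucose transporter SLC2A1 (0.49). Of 38 nuclear-encoded oxidative phosphorylation genes, 5 rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.00016; adjusted p = 0.45 with an estimated correlation), UQCRC1 by 0.19. Of 25 drug efflux and metabolism genes, 9 rose and 2 fell on both adjustments (camera adjusted p = 0.027; adjusted p = 0.18 with an estimated correlation), with ALDH3A1 higher and CYP1B1 lower (-0.36). Without near-identical gene families the camera adjusted p was 0.16. Of 24 immediate early genes, 11 fell and 1 rose (11 and 2 adjusted over the list alone; camera adjusted p = 0.0031; adjusted p = 0.22 with an estimated correlation), with the ERK phosphatases DUSP6 (-0.81) and DUSP5 (-0.60) lower.

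Calls of a few lists at 24 h were lost when 1 library was left out. Epithelial identity had 10 higher and 2 lower of 25 (11 and 2 adjusted over the list alone; camera adjusted p = 0.035; adjusted p = 0.45 with an estimated correlation). JUP was higher (0.36) and CLDN1 lower (-0.62), and the list lost its call without control replicate 4 (0.096) or 24 h replicate 1 (0.074), or without near-identical gene families (0.081). CDH1 was at 0.05 (limma adjusted p = 0.53). Mesenchymal genes had 7 higher and 2 lower of 31 (12 and 2 adjusted over the list alone; camera adjusted p = 0.04; adjusted p = 0.32 with an estimated correlation). TGFBI (0.34) and COL1A1 (0.55) were higher, and the list lost its call without control replicate 2 or 4 (0.051 and 0.089) or 24 h replicate 1 or 3 (0.062 and 0.057). Heat shock proteins had 6 higher and 2 lower of 21 (6 and 3 adjusted over the list alone; camera adjusted p = 0.04; adjusted p = 0.45 with an estimated correlation), CRYAB by 1.08 and HSPB1 by 0.88. They lost it without control replicate 2 or 3 (0.052 and 0.12), without 24 h replicate 1, 2 or 4 (0.063, 0.052 and 0.072), without a composition factor (0.078) and without near-identical gene families (0.063).

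The remaining lists did not pass at 24 h (camera adjusted p in brackets). These were p53 targets, with 6 higher and 4 lower of 30, and 8 and 5 adjusted over the list alone (0.52). Others were endoplasmic reticulum chaperones (0 and 2 of 25, and 0 and 1 adjusted over the list alone; 0.45) and the integrated stress response (8 and 2 of 29, and 9 and 5 adjusted over the list alone; 0.2). Interferon-stimulated genes had 4 and 5 of 29 on both adjustments (0.95, towards lower values, with a median of 0.03 and a mean of 0.01). CDKN1A rose by 0.30 and GDF15 by 0.61, and MDM2 was at 0.00 (limma adjusted p = 1). TGF-beta targets had 6 and 5 of 22, and 7 and 10 adjusted over the list alone (0.89), and YAP and TAZ targets 2 and 5 of 23 on both adjustments (0.38). Metallothioneins had 1 and 3 of 6 on both adjustments (0.23), and stem-associated genes 4 and 2 of 19 on both adjustments (0.8), with CD24 at 0.55. Glycolysis had 3 and 2 of 16 on both adjustments (0.45), and cholesterol synthesis 2 and 5 of 25, and 2 and 6 adjusted over the list alone (0.45). Fatty acid synthesis had 4 and 1 of 18, and 4 and 2 adjusted over the list alone (0.071; 0.039 without 24 h replicate 4). Luminal markers had 4 and 2 of 9 on both adjustments (0.45), and stromal markers 2 and 2 of 6 on both adjustments (0.84). Ribosomal proteins had 0 and 1 of 74, and 0 and 0 adjusted over the list alone (0.78; 0.017 without 24 h replicate 4), and mitochondrially encoded transcripts 0 and 0 of 13 on both adjustments by limma (0.33). Of these 13, 1 had an unadjusted limma p under 0.05, and limma-voom called 1. Of the tested blood and immune markers, CSF1R (0.59), CD68 (0.29) and CD14 (0.28) were higher, and KDR was at 0.29 (limma adjusted p = 0.15; higher when adjusted over the list alone).

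**Figure D3:**
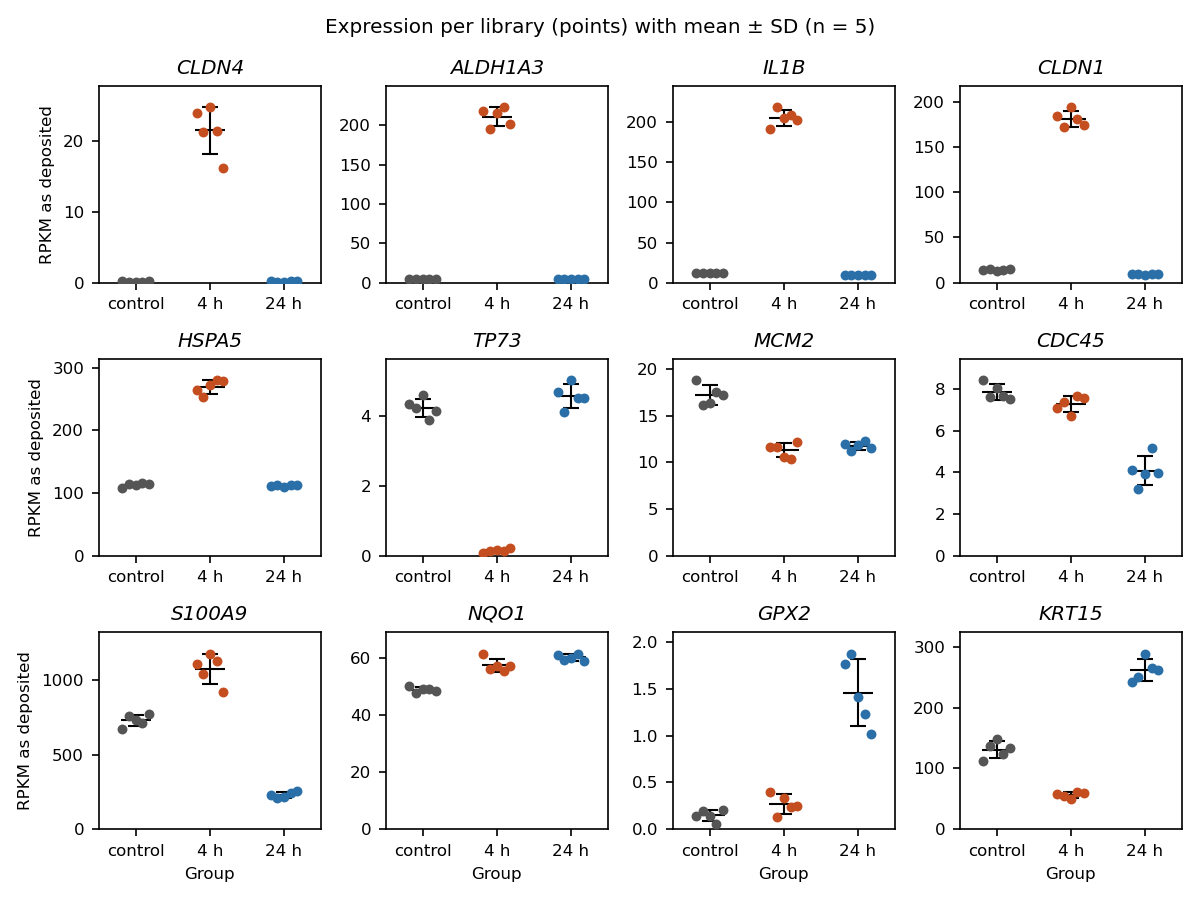
RPKM as deposited (y axis, linear, from 0) of 12 genes in the control, 4 h and 24 h groups (x axis), 1 point per library, with bars for the mean ± SD (n = 5). CLDN4, ALDH1A3, IL1B, CLDN1 and HSPA5 are high at 4 h only, TP73 is low at 4 h only, and CDC45 and S100A9 are lowest and GPX2 and KRT15 highest at 24 h.

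The comparison of 24 h with 4 h is also the test of whether the change against control differed between the times. FST, CLDN4 and ALDH1A3 were near their control levels at 24 h, at 0.31 ± 0.178, 0.166 ± 0.0366 and 4.56 ± 0.284 RPKM (SD, n = 5), whereas PLA2G4E stood below control (log2 -1.07). The log2 changes from 4 h were -6.68 ± 0.25, -6.48 ± 0.18 and -5.65 ± 0.052, in the same order (SE; limma adjusted p = 1.3e-12, 3.2e-14 and 4.5e-20). SPRR2D, PLA2G4E, SPRR2A, OVOL1, SERPINB2, SERPINB10 and IL1B completed the 10 largest falls, from -6.58 to -4.51. Under the same filter the largest rises were those of TP73 (4.10), MYCL (3.42) and VAV3 (3.39), followed by GPR1, SEMA6D, FIBIN, PDK4, GNAO1, GRAMD2 and KLHDC8B, the last at 2.89. PDK4, the kinase that shuts pyruvate out of oxidation, went from 0.757 ± 0.228 to 7.48 ± 0.151 RPKM (SD, n = 5). In all, 9788 genes differed, 4718 higher and 5070 lower at 24 h, of which 814 and 776 by at least 2-fold. Without a composition factor 64.9% of these calls were higher, against 48.2%, and the median of all genes moved by 0.15.

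Between 4 h and 24 h the endoplasmic reticulum list fell (24 of 25 lower and 0 higher on both adjustments; camera adjusted p = 9.2e-09), and among the 31 lists this was the only call of this comparison that held with an estimated correlation (adjusted p = 0.022). By camera adjusted p, epithelial identity (20 lower, 3 higher of 25; 5.4e-06), basal and squamous genes (21 and 5 of 29; 0.00072) and DNA replication (35 and 2 of 41; 2e-04) were lower at 24 h (adjusted p = 0.21, 0.26 and 0.29 with an estimated correlation). Metallothioneins (6 and 0 of 6; 0.0051) and TGF-beta targets (17 and 4 of 22; 0.008) were lower as well (adjusted p = 0.11 and 0.26 with an estimated correlation). YAP and TAZ targets (16 lower and 4 higher of 23), immediate early genes (16 and 6 of 24), heat shock proteins (14 and 5 of 21) and luminal markers (7 and 1 of 9) were lower too, each with a camera adjusted p of 0.011. With an estimated correlation the adjusted p was 0.26, 0.29, 0.29 and 0.21. NF-kB genes (14 and 6 of 25; 0.026), glycolysis (12 and 2 of 16; 0.032) and stem-associated genes (11 and 4 of 19; 0.036) were also lower (adjusted p = 0.3, 0.51 and 0.21 with an estimated correlation). Counts adjusted over the list alone were the same for all lists named so far in this comparison. Without near-identical gene families the camera adjusted p was 0.067 for NF-kB genes and 0.071 for luminal markers, and without a composition factor it was 0.19 for glycolysis. That of stem-associated genes was 0.065 under the filter on a CPM of at least 1 in 5 libraries.

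By the camera adjusted p in brackets, lists higher at 24 h than at 4 h were p53 targets (20 higher and 9 lower of 30; 0.011), peroxide removal (16 and 4 of 25, 16 and 5 adjusted over the list alone; 0.011) and oxidative phosphorylation (25 and 1 of 38; 0.0086). Their adjusted p with an estimated correlation was 0.25, 0.29 and 0.53. Other replication-dependent histones (7 and 0 of 9; 0.02) and NRF2 targets (19 and 10 of 30; 0.031) were higher too (adjusted p = 0.26 and 0.29 with an estimated correlation). G2 and mitosis (23 higher and 10 lower of 41; 0.036), drug efflux and metabolism (17 and 7 of 25; 0.039) and fatty acid synthesis (10 and 5 of 18; 0.039) were higher as well (adjusted p = 0.67, 0.26 and 0.24 with an estimated correlation). Counts of these lists adjusted over the list alone were the same except where given. The G2 and mitosis call was lost without 4 h replicate 1 (0.053) or 24 h replicate 1 (0.054), and that of fatty acid synthesis without 24 h replicate 1 (0.052). HIST1H3E and HIST1H3H were higher at 24 h than at 4 h by 1.81 and 1.60. The drug efflux list had a median of 0.3 and a mean of 0.07, and lost its call without a composition factor (0.1) or without near-identical gene families (0.095).

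Lists that did not pass between the times are given with genes higher and lower at 24 h and the camera adjusted p. DNA repair had 9 and 22 of 43 (0.16), the integrated stress response 10 and 11 of 29 (0.87), interferon genes 8 and 13 of 29 (0.56), and hypoxia genes 12 and 9 of 24 (0.54, with a median of 0.1 and a mean of -0.15). Cholesterol synthesis had 7 and 14 of 25 (0.096), mesenchymal genes 11 and 14 of 31 (0.76; median -0.05, and 0.11 without a composition factor), and stromal markers 2 and 4 of 6 (0.87, towards higher values, with a median of -0.24). All of these counts were the same adjusted over the list alone. Ribosomal proteins had 8 and 2 of 74, and 1 and 0 adjusted over the list alone (0.38, and 2.8e-05 without a composition factor), and H3.3 and H3 chaperones 4 and 11 of 21, and 4 and 12 adjusted over the list alone (0.14). Of 13 mitochondrially encoded transcripts, 10 were higher and 1 lower on both adjustments (0.059). That list passed without 4 h replicate 2, 3 or 4 (0.032, 0.044 and 0.044) or 24 h replicate 1 (0.045), with limma-voom (0.024), without a filter (0.038), under the replicate block (0.031) and by fry (0.037). KDR (2.12) and CSF1R (1.78) were higher at 24 h than at 4 h, as was CD14 (0.42).

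Against control, 803 genes changed in the same direction at both times (401 higher, 402 lower) and 1132 in opposite directions, 569 of them higher at 4 h and lower at 24 h. Independent sets of these sizes would share 418.2 higher and 431.2 lower genes and give 441.2 and 408.7 opposite ones. Unchanged groups simulated against the same controls shared 0 genes in either sense. No simulated set had calls at both times, so that result was fixed and says nothing about the overlap. With the control libraries split between the comparisons, the median was 406 genes in the same direction and 634 in opposite directions. The correlation of log2 changes across genes, which are not independent replicates, was 0.0047, against 0.5 for simulated unchanged groups and -0.0346 with split controls. The 0.5 arises from the shared controls with no change present, so it is no reference for the correlation of real changes. The covariance was 0.00076 against 0.00811 in the simulation, a difference of -0.0073. Among genes called in opposite directions were S100A9, S100A8, KRT15 and CLDN1, and among those called in the same direction MCM2, SOD2, NQO1, KRT8 and CD24.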

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

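The tests of other splits of the libraries and of library composition were chosen only after the results were seen, and the tests of GC content and transcript length and of time in culture before. Dixon's test, applied to each group of 5 libraries, marks a library far from the other 4, and chance marks about 1 in 20 groups. It marked 4 of 21 groups of library measures and 31 of 465 groups of gene values.

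Among library measures, 4 h replicate 2 had 15.5 M reads (11 to 11.9 M in the other 4) and 21400 genes detected (20200 to 20500). The 24 h replicate 1 library had the lowest mitochondrial share of its group, 3.09% (3.54% to 3.67%), and the highest second principal component, 19.5 (10.7 to 13.3). It also had the lowest MT-ND4 and MT-CYB of its group, 2840 and 1850 RPKM (3320 to 3430 and 2220 to 2260).

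In control libraries, replicate 1 stood apart for ABCC2 (35.2 RPKM), ABCC3 (12.2 RPKM) and SOD2 (65.6 RPKM), and replicate 2 for FOSL2 (41.4 RPKM). Control replicate 4 stood apart for MDM2 (10.7 RPKM) and KRT83 (19 RPKM), and replicate 5 for SRGAP3 (2.86 RPKM) and TP63 (18.7 RPKM). At 4 h, replicate 3 stood apart for WISP2 (0.759 RPKM), NT5E (13.7 RPKM) and SLC7A11 (1.59 RPKM). The 4 h replicate 4 library did so for ZNF608 (0.155 RPKM), MT1E (249 RPKM), HSPB1 (672 RPKM), TPM4 (150 RPKM) and KRT81 (2520 RPKM). The 4 h replicate 5 library did so for SERPINB2 (112 RPKM), BEST1 (0.306 RPKM) and TXNIP (49.1 RPKM). At 24 h, replicate 2 stood apart for ALDH1A3 (5.06 RPKM), GCSAM (2.23 RPKM) and HMOX1 (1.32 RPKM), and replicate 3 for CLDN1 (8.44 RPKM), HIST1H2AC (17.9 RPKM) and HBEGF (1.22 RPKM). Replicate 4 at 24 h stood apart for FOSL2 (39.4 RPKM), MT1E (191 RPKM) and HIST1H3E (3.14 RPKM), and replicate 5 for SPRR2A (1.33 RPKM).

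The change against control differed between 4 h and 24 h for 9788 genes by limma and 21 gene lists by camera, tested directly as the difference between the times. Of the 155 genes with library values examined here, 149 differed, and 55 were called in opposite directions at the times. Many of the 155 were named because they changed, so these counts partly restate that choice. Over all tested genes, 69.2% differed between the times. Of the 9339 genes called at 4 h, 1935 were also called at 24 h.

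The libraries were regrouped to look at chance, with 100 splits of the 10 libraries, the real one included, for each comparison. For genes, 1 of 100 splits, the real one, reached 9339 calls at 4 h, 2573 at 24 h and 9788 between the times. The highest of the others were 1, 3 and 73. A mixed split puts the difference between the groups into the spread within each, so few calls were likely from it. The splits therefore do not decide whether chance differences between samples had a part. Random assignments of all 15 libraries to the 3 groups called up to 5970 genes at 4 h and 5736 at 24 h. Such an assignment can put most 4 h libraries into 1 group and so keep much of the real difference, so these numbers do not measure chance. For the 803 shared genes the real assignment was also the only 1 of 100 to reach that number, and the highest other was 0. That says nothing about the overlap, since 0 of the other 99 assignments called genes at both times and so none could share any. Independent sets would share 418.2 higher and 431.2 lower genes, against 401 and 402 found. For gene lists by camera with the preset correlation, 3 of 100 splits reached the real 14 at 4 h, with 15 as the highest other. At 24 h 2 of 100 reached 16 and between the times 2 of 100 reached 21, with the same numbers, 16 and 21, as the highest others. These shares lie under 0.05, but other splits passed as many lists. Each of those splits keeps part of the difference between the groups, and camera compares a list with other genes, so lists can pass from that part. The splits thus do not decide the question for lists either, and the number passing with that correlation is not taken as evidence for or against chance.

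DNA replication genes were lower at 24 h than in controls, 39 of 41 at a median of -0.43. Leaving out the composition factor, which moves every gene of a library alike, moved the median of all genes at 24 h by -0.024. A shift of that size is too small to be the whole cause of this fall. The list kept its call without the factor (camera adjusted p = 2.5e-28, median -0.46), but so small a shift could hardly undo it. GC content and transcript length were argued against as the whole cause. After correction the camera adjusted p was 3e-30 and the median -0.44, and all 41 members had values. A longer time in culture may give such a fall as cells grow dense, and it cannot be told apart from D-alanine, since 0 control libraries are labelled with a time. An effect of D-alanine therefore stays open alongside it as a hypothesis.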

How the results depend on the processing

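The tests without a composition factor, with other pseudocounts and without near-identical gene families, and those of lists and shared genes under other scalings, filters and voom, were chosen only after the results were seen. Limma counts of changed genes stayed within 1.5 times of those reported in all settings that kept every library, at 9271 to 10132 for 4 h, 1992 to 3029 for 24 h and 9556 to 10564 between the times. Without a composition factor, genes higher at 4 h numbered 3077 (4723 as reported) and genes lower 7055 (4616), because the factor moves every gene of a library alike. Of the calls reported, 7693, 2342 and 8296 kept their direction and passed without the factor, and 35, 0 and 13 were called in the other direction. With upper-quartile factors 56.3% of the calls at 24 h were higher. Between the times, log2 values of NQO1 (0.07), VIM (0.04) and FN1 (0.01) lay above 0 without the factor, against -0.09, -0.11 and -0.14 as reported.

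With an estimated correlation, 1, 4 and 1 lists passed at 4 h, at 24 h and between the times, against 14, 16 and 21 with the preset one. With fry, which does not compare a list with other genes, 25 lists passed at 4 h, and the cause of these differences between list tests was not tested. By fry the drug efflux list pointed the other way at 4 h (adjusted p = 5.9e-06, against 0.38 by camera) and between the times (0.014, against 0.039). At 4 h its median (-0.13) and mean (0.06) differ in sign, and between the times the cause was not tested. With the controls split between the comparisons, 406 genes were shared, against 803, with fewer control libraries in each. Other settings gave 614 to 987 shared genes. Other list calls gained or lost in some settings, such as cholesterol synthesis at 4 h without a filter (0.025), were not followed further, and the cause was not tested.

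Counts of genes changed at least 2-fold depended on low genes. Without a filter, 1135 fell at 4 h (702 as reported), 65 rose and 70 fell at 24 h (42 and 34), and 1271 rose between the times (814). With a pseudocount of 1, which shrinks low genes by construction, these counts were 199, 12, 8 and 276, and 513 fell between the times (776). Few reads thus limit folds of genes near 0, and the totals of 8523761 to 15463949 reads left ABCG2 with 7 to 19 reads per group.

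Leaving out each library in turn gave 9019 to 9139 changed genes at 4 h (4584 to 4757 higher, 4344 to 4497 lower), 2010 to 2472 at 24 h (958 to 1293 higher, 974 to 1222 lower) and 9425 to 9644 between the times (4445 to 4694 higher, 4921 to 5111 lower). Lists passing numbered 13 to 14, 13 to 17 and 20 to 22, and shared genes 606 to 784.

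The replicate number as a block gave 9271, 2305 and 9721 genes, 13, 14 and 22 lists and 722 shared genes. Under the block the calls of stem-associated genes at 4 h (0.061) and of heat shock (0.057) and mesenchymal genes (0.06) at 24 h did not pass, and mitochondrially encoded transcripts passed between the times (0.031). The numbers were not taken as pairs because the labels do not say that they mark any. Deviations of libraries with the same number correlated at -0.069 to 0.2, over 0.1 in 1 of 15 pairs, and 5 libraries correlated best with their own number. That 1 pair was replicate 1 at 4 h and at 24 h (0.2, against at most -0.026 with other numbers). Both had the lowest mitochondrial share and the highest second principal component of their groups, and a shared origin was not tested. DESeq2, planned for counts, was not run because the unit is RPKM.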

Other observations

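The 4 gene lists, the genes named here, and the tests of composition, another cell line and KRT81 reads were chosen only after some of the values had been seen, and the tests of GC content and of medium before.

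Most listed genes that respond to growth factors and to actin dynamics were higher at 4 h. Of 23 ERK feedback and EGF receptor ligand genes, 21 rose and 0 fell, with a median log2 change of 1.23 (camera adjusted p = 1.2e-10; adjusted p = 0.0056 with an estimated correlation). TGFA, a ligand of the EGF receptor, rose from 4.85 ± 0.334 to 22.9 ± 1.57 RPKM (SD, n = 5), PHLDA1 rose by 2.39 on the log2 scale, SPRY4 by 1.43 and HBEGF by 1.21. All 17 tested actin and SRF target genes rose, with a median of 1.15 (1.5e-12; adjusted p = 0.0081 with an estimated correlation). The immediate early genes EGR1 and FOS, tested but in neither list, went the other way at 4 h. Mean EGR1 fell from 30.2 to 9.79 RPKM and mean FOS from 7.95 to 5.05 RPKM. Both lists were written after some values had been seen, so their counts do not stand for all genes of these responses. ACTB, beta-actin, which is often used as a reference gene, rose from 1066 ± 50.8 to 3574 ± 87.2 RPKM (SD, n = 5), VCL, vinculin, by 1.77 and TPM4, a tropomyosin, by 2.09. At 24 h the ERK list was below control, with 18 of 23 lower and 1 higher at a median of -0.38 (1.9e-12; adjusted p = 0.0055 with an estimated correlation), DUSP6 going from 1.00 at 4 h to -0.81.

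Target genes of the glucocorticoid receptor and of FOXO factors were lower at 4 h. Of 17 glucocorticoid targets, 11 fell and 4 rose, at a median of -0.98 (camera adjusted p = 0.00014; adjusted p = 0.0056 with an estimated correlation). TSC22D3 fell by 2.21 on the log2 scale, KLF9 by 2.11, PER1 by 1.32 and FKBP5 by 0.55, and NR3C1, the receptor gene itself, fell from 11.6 ± 0.48 to 5.69 ± 0.429 RPKM (SD, n = 5). Of 19 FOXO targets, 16 fell and 3 rose, at a median of -1.11 (9e-07; adjusted p = 0.0081 with an estimated correlation). TXNIP, an inhibitor of thioredoxin, went from 226.5 ± 9.8 to 56.3 ± 4.21 RPKM at 4 h and 313 ± 7.62 RPKM at 24 h (SD, n = 5). At 24 h glucocorticoid targets (7 higher and 1 lower; camera adjusted p = 0.00099, and 0.009 with an estimated correlation) and FOXO targets (8 and 1; 1e-04 and 0.026) were above control, at medians of 0.07 and 0.12. The actin list was below it (1 and 6; 0.0049), a call lost with an estimated correlation (0.24). Between the times the ERK and actin lists fell and the other pair rose, with camera adjusted p of 3.5e-05 or less, and of 0.01 or less with an estimated correlation. Because values of many members had been seen, members not yet looked at were tested alone. Of 8 such actin genes 8 rose (camera adjusted p = 2.9e-06) and of 6 ERK genes 4 rose (0.031). The 2 glucocorticoid genes and 1 FOXO gene (0.081 each) lie under the minimum of 5 members, so those values decide nothing. All of these used the preset correlation, and whether they hold with an estimated one was not tested. The calls of the glucocorticoid and FOXO lists thus rest almost wholly on genes whose values had been seen. At 24 h the 6 ERK and 8 actin genes, each with 1 higher and 2 lower, did not pass (0.14 each). Exons of VCL overlap a gene on the other strand and those of PER1 one on the same strand, so both values are uncertain.

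These lists hold known targets and do not measure the activity of a receptor or kinase, and no biological explanation was tested. Leaving out the composition factor, which moves every gene of a library alike, moved the median of all genes at 4 h by -0.17. The list medians were then -1.16 for glucocorticoid, -1.28 for FOXO, 1.05 for ERK and 0.97 for actin genes. A shift of that size is too small to be the whole cause of this pattern. That 4 of 4 lists kept direction and call adds little, since so small a shift could hardly undo them. GC content and transcript length are argued against as the whole cause, with 4 of 4 lists kept after correction. Libraries of another cell line are argued against, since 0 of 7002 protein-coding genes at 5 RPKM or more in controls were under 0.25 RPKM at 4 h, although that limit was set after values were seen and 1 gene, TP73, would count as lost at 4 RPKM. A change of medium or handling at the addition of D-alanine cannot be told apart from D-alanine itself, because 0 control libraries are labelled with a time, and the growth medium holds EGF, insulin and hydrocortisone per the labels.

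KRT83, a hair keratin, differed widely between libraries of 1 group, with 39 to 4219 reads at 4 h. KRT81, its abundant neighbour in sequence, shares 6.41% of the 50-base words of KRT83. Reads shared with KRT81 are argued against only where they would be a steady share of KRT81 reads. KRT83 reads ran from 0.0666% to 5.55% of KRT81 reads at 4 h, a ratio of 83.3, and the ratios were 25.1 in controls and 46 at 24 h. KRT81 ran only from 54295 to 81274 reads at 4 h, so the ratio there mostly restates the spread of KRT83. Single libraries carried the ratios at 4 h (2.84 without replicate 5) and in controls (2.49 without replicate 4), but at 24 h it stayed at 18.4 or more without any 1 library. The share was alike in some libraries of different groups. It was 1.78% in control replicate 4, 1.97% and 1.96% in 4 h replicates 3 and 4, and 1.86% and 1.84% in 24 h replicates 1 and 4. The other libraries lay at 0.177% or lower, or at 4.65% to 5.55%. Reads from KRT81 at a share that differs between libraries thus stay open. KRT83 also shares 4.38% of its 50-base words with KRT86, and reads from that gene were not examined. Another candidate is a difference between the samples themselves, such as rare cells that express KRT83, which was not tested.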
